A study of Mus musculus with 9 samples.

How the data were processed

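Small RNA libraries were made from the milk fat of 9 dams, 5 on a control diet and 4 on a high-fat diet. Per the labels' protocols, milk was spun, the fat layer was washed with phosphate-buffered saline and spun again to remove cells and debris, total RNA was extracted with a column kit, and libraries were prepared with the NEXTflex small RNA kit and sequenced on a HiSeq2500 instrument. The washing step matters for the measurements because milk cells left in the fat would add their own miRNAs. Dams were housed in pairs within a diet before mating, and which dams shared a cage is not given in the sources used here, so cage could not be entered in any model. Dams are the replicates, and no sequencing batch or date is given in the sources used here.

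The deposited table holds read counts of known miRNAs, 1 row per pair of precursor and mature name and 1 column per dam. Per the submitters' processing notes, adapters were trimmed with cutadapt 1.9.1 and the genome build was GRCm38. The aligner, the counting tool and the miRBase release are not given in the sources used here. The kit adds random bases at the adapters, and whether these were trimmed or used to merge PCR copies is also not given in the sources used here, so counts were taken as reads, not molecules. The deposited counts are whole numbers written with comma separators in 833 cells, and the separators were removed on reading. Libraries were matched to dams by the sample names in the column heads. The table has 2059 rows with 1915 mature names and 1193 precursor names. A mature miRNA encoded by several precursors has several rows, 81 names in all. Of the 63 of these that were detected, 39 had equal counts in every row. Equal rows would arise if a read that fits several precursors was counted for each, but the counting rule is not given. In each library, the highest count among the rows of a name was therefore kept, so that a read counted in several rows was not summed. Where rows differ, libraries may take their counts from different rows. A read may also have been counted under several mature names where their sequences are alike. In all, 22 names fell into 9 sets with identical or nearly identical counts. These include miR-199a-3p with miR-199b-3p, miR-486a-5p with miR-486b-5p, and several names of the Sfmbt2 intron cluster. Such names cannot be told apart, and each set was entered once in list shares. Tests of single names, camera, fry and counts of list members entered every name separately, apart from a fit with identical names merged.

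Libraries of one diet were compared before averaging, and the lowest chi-square per degree of freedom between any pair was 58.3, so none was a repeat of another. Totals after keeping 1 count per name in each library ran from 837817 in control library 5 to 3897109 in high-fat library 2. A count of 0 allows up to 3 counts, which is 0.000358% of the smallest library and 7.70e-05% of the largest. Single-library shares carry 95% Wilson intervals, and these intervals and floors cover counting error only.

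The test fixed before the data were examined was the quasi-likelihood test of edgeR on these counts, with the Wald test of DESeq2 as an alternative, and the values reported here do not come from either. The Wald test was not run, and an exploratory edgeR fit was seen but is not reported. Because of the comma separators the columns did not pass an automatic check as plain counts and were recorded under another unit, for which count models are ruled out here. The values themselves are raw read counts. limma-voom, which had been listed beforehand as an alternative, was used in their place for every result that had been planned on the count model, and camera and fry were run on its output. The sample groups, the filter, the normalization, the thresholds, the miRNA lists and the rule for named miRNAs stayed as fixed.

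Mature miRNAs were tested if they reached 10 counts, scaled to the median library as 5.25 CPM, in at least 4 libraries and 15 counts in total. The names left out held 0.0470% of all counts. Library sizes were scaled with trimmed mean of M values factors, with 30% of the log ratios and 5% of the levels trimmed from each end, written out in R 4.3.3. limma 3.58.1 fitted log2 CPM with voom weights, with diet as the only term, and gave moderated tests that were two-sided and adjusted by the Benjamini-Hochberg method over the 312 tested names. Fold changes are high-fat over control on the log2 scale with their standard errors, and CPM values use the scaled library sizes. The 25 lists of families, clusters, functions and marker miRNAs of other cell types were among the choices fixed beforehand. camera compared each list of at least 3 tested members with the other miRNAs at a preset correlation of 0.01, and was repeated with an estimated correlation. fry asked whether the members move on balance one way. List shares, total counts, the number of detected miRNAs after thinning to 837817 counts, the share of the 10 most abundant, the entropy, the spread between dams and the first principal component (log2 CPM with a prior count of 2) were compared by exact permutation over all splits, two-sided as 2 times the smaller tail. Arm ratios used log2 of 5p over 3p counts with 0.5 added to each, for 102 precursors with a mean of at least 10 counts in both arms, tested with limma with a trend. Of these pairs, 20 have an arm that other precursors share.

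The miRNAs named are the 15 with the highest mean share, the 12 with the smallest p, since fewer than 12 passed the threshold, the members of each list that passed over all miRNAs or over the list alone, otherwise up to 3 of its most abundant, and the 5 arm pairs with the smallest p. Others are said to have been chosen after their values were seen. Positions are those of the precursor genes in GENCODE release M21 on GRCm38, matched by name, and 77 of 85 names looked up were placed. A gene was put in an exon if an exon of any annotated transcript of the host covered it, which does not show how it is processed. let-7f, let-7g, let-7i, miR-142a, miR-146a, miR-486a, miR-486b and miR-92a were not matched by the rule that turned precursor names into gene names. This does not show that their genes are absent there. The same rule found no sequence of the tested let-7 names for the word search. Precursor sequences of 277 tested names were split into 20-base words and searched in the transcripts of all other genes but miRNA genes, on both strands, outside the genes that overlap the precursor.

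The steps were tested on simulated data before use. Counts were drawn for the 828 detected names with the real means, library sizes and spread, and 200 names were changed in high-fat libraries. Over 20 simulations of the comparison of high-fat with control, limma-voom called 26.7% of tested names changed 1.5-fold, 54.2% of those changed 2-fold, 80.0% of those changed 4-fold and 86.0% of those changed 8-fold, and 3.25% of its calls were unchanged names. These shares hold for many changed names, since the adjusted p depends on how many there are. A list of 8 names changed 2-fold had an unadjusted camera p under 0.05 in 100% of the simulations, and unchanged lists in 0%. The simulated names were abundant and drawn independently of each other. Estimated correlations within the real lists ran up to 0.968, in the erythrocyte list. Its 3 tested names include miR-486a-5p and miR-486b-5p, which have nearly identical counts. The share of 100% therefore does not carry over to adjusted p of the real lists. Among the 102 arm pairs, 79.2% of those changed 4-fold were called.

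Alternatives fixed beforehand were other library scalings (median of ratios, totals alone, upper quartile), no count filter or a filter of 10 CPM in 4 libraries, the replicate number as a block, rows of one name summed or kept apart, the most abundant miRNA left out, quality weights per library, a robust variance prior, a threshold of 0.10, fry, other pseudocounts, count minimums and numbers of top miRNAs, and each library left out in turn. Added after the data were seen were a fit without high-fat libraries 1 and 3, a fit with identical names merged, principal components without miR-3470a and miR-3470b, and estimated correlations in the fits whose camera calls differed. Python 3.11.15 with pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the figures.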

Results

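Small RNA was sequenced from the washed fat layer of milk taken on lactation day 10 from 9 first-litter ICR (CD1) mouse dams, an outbred stock. Milk fat carries cytoplasm of the secretory epithelium that is released with each fat globule, so its RNA is read as a sample of the milk-producing cell. From 4 weeks of age, 4 weeks before mating, and through pregnancy and lactation, 5 dams ate a control diet with 10% of its energy as fat and 4 dams a high-fat diet with 60%. Sucrose supplied 7% of the energy in both diets, which held 3.85 and 5.24 kcal per g. Each library came from a different dam. Total mature miRNA counts were 1684296, 1244704, 2750482, 1599611 and 837817 in control libraries 1 to 5, and 2335910, 3897109, 2022572 and 1905838 in high-fat libraries 1 to 4. Of 1915 mature miRNA names in the count table, 828 had at least 1 count, and 312 passed the filter on low counts and were tested. With 9 libraries in groups of 5 and 4, no two-sided exact permutation p below 0.0159 can be reached.

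The 15 most abundant miRNAs of milk fat were compared between diets. miR-146b-5p, a feedback regulator of inflammatory signalling, held 20.8% ± 1.85 of the counts in control milk (SD, n = 5) and 20.1% ± 1.28 in high-fat milk (SD, n = 4). miR-148a-3p, the best known milk miRNA, held 12.9% ± 1.97 and 13.8% ± 0.885, and miR-30a-5p held 6.87% ± 0.920 and 6.42% ± 0.716. The gene of miR-146b lies on chromosome 19 at 46342762 to 46342870 in an intron of Mfsd13a, that of miR-148a on chromosome 6 at 51269812 to 51269910 between genes, and that of miR-30a on chromosome 1 at 23272269 to 23272339 between genes (GRCm38). miR-21a-5p, whose gene lies in an exon of Vmp1 on chromosome 11 at 86584067 to 86584158, held 6.50% ± 1.10 of control counts and 4.47% ± 1.17 of high-fat counts. It was the only one of the 15 most abundant miRNAs that was also among the 12 with the smallest p. miR-181a-5p held 3.99% ± 0.981 and 4.61% ± 1.15. The other 10 were miR-200b-3p, let-7i-5p, miR-200a-3p, let-7f-5p, let-7g-5p, miR-200c-3p, miR-26a-5p, miR-30e-5p, miR-27b-3p and miR-143-3p, each with a mean share between 1.46% and 3.45% in either diet. The log2 fold change largest in size among the 15 was -0.55, that of miR-21a-5p, and none of the 15 passed limma-voom at an adjusted p of 0.05. miR-143-3p, a miRNA of smooth muscle and other stromal cells, measured 26084 CPM in high-fat library 4 and at most 12261 CPM in the other 3 high-fat libraries, so that 1 library decides its mean of 1.52% ± 0.672 in high-fat milk.

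**Figure D1:**
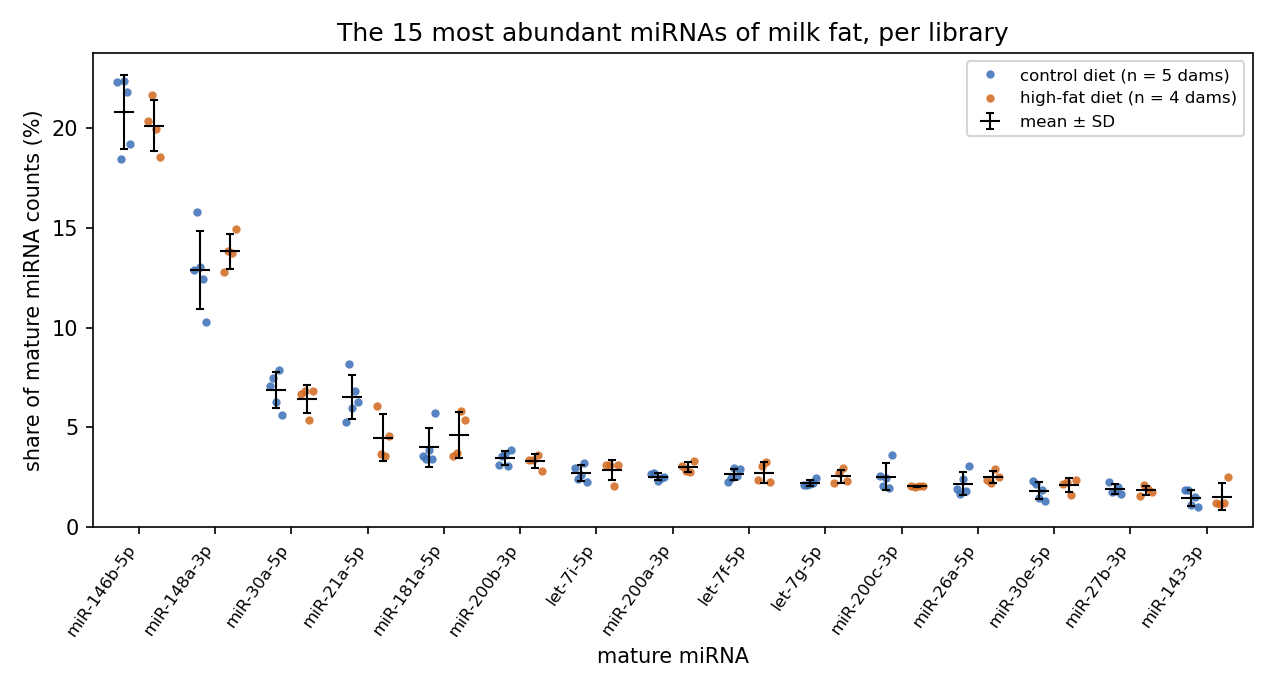
Share of all mature miRNA counts, in percent, of the 15 most abundant mature miRNAs. Each point is the library of 1 dam, blue for the control diet (n = 5) and orange for the high-fat diet (n = 4), with the mean and SD in black. miR-146b-5p held about 20% of the counts in both diets, with 20.8% in control and 20.1% in high-fat milk.

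The main question was whether the diet changed the miRNAs that dams secrete into milk. None of the 312 tested mature miRNAs passed an adjusted p of 0.05 by limma-voom, and the smallest adjusted p was 0.0996. An unadjusted p below 0.05 was found for 32 miRNAs, 14 with a higher and 18 with a lower level in high-fat milk, where 15.6 are due by chance. With a weight for the quality of each library, limma-voom called 2 miRNAs, miR-574-5p and miR-10b-5p, and without control library 5, the shallowest, it called 4, miR-574-5p, miR-10b-5p, miR-3470a and miR-3470b.

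Of the 12 miRNAs with the smallest p, all of which missed the adjusted threshold, 6 had a higher mean level in high-fat milk and 6 a lower one. miR-574-5p measured 53.9 ± 15.8 CPM (read counts scaled by library size) in control and 113 ± 21.1 CPM in high-fat milk, a log2 fold change of 1.13 ± 0.22 (SE), and all 4 high-fat libraries lay above all 5 controls. Its gene is in an intron of Fam114a1 on chromosome 5 at 64970318 to 64970395. Its precursor shares 20-base words with transcripts of 85 other genes, so reads from elsewhere may be counted under its name. Whether the shared words lie in the mature sequence that was counted was not tested. miR-10b-5p, encoded among the Hox genes that pattern the body axis, measured 29.0 ± 13.1 CPM in control and 131 ± 65.0 CPM in high-fat milk, a log2 fold change of 2.11 ± 0.44, again with 4 of 4 high-fat libraries above every control. Its gene lies on chromosome 2 at 74726070 to 74726137, in an intron of both Hoxd3 and Hoxd4. Its relative miR-10a-5p, from chromosome 11 at 96317165 to 96317274 between genes, measured 1297 ± 507 and 2270 ± 526 CPM, a log2 fold change of 0.89 ± 0.28. For both miR-574-5p and miR-10b-5p limma-voom gave an adjusted p of 0.0996.

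miR-32-5p, in an intron of Tmem245 on chromosome 4 at 56895229 to 56895298, had a log2 fold change of 0.91 ± 0.23 and an adjusted p of 0.170 by limma-voom. miR-141-3p, a member of the miR-200 family that keeps cells epithelial by repressing Zeb1 and Zeb2, held 0.450% ± 0.0640 of control and 0.795% ± 0.275 of high-fat counts, and its log2 fold change was 0.77 ± 0.21. miR-181c-5p had a log2 fold change of 0.59 ± 0.17, from 584 ± 38.6 to 899 ± 214.6 CPM. miR-32-5p, miR-141-3p and miR-181c-5p each lay above all 5 controls in 4 of 4 high-fat libraries.

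miR-3470a and miR-3470b had the largest differences of the 12. miR-3470a measured 97.3 ± 123 CPM in control and 5.35 ± 1.93 CPM in high-fat milk, a log2 fold change of -3.44 ± 0.83, and miR-3470b 107 ± 134 and 3.07 ± 1.65 CPM, a log2 fold change of -4.41 ± 1.12. For both the adjusted p was 0.170 by limma-voom, and 4 of 4 high-fat libraries lay below all 5 controls. The control mean rested on control library 5, which held 267 counts of miR-3470a and 291 of miR-3470b. Their precursors, on chromosome 6 at 83090311 to 83090387 between genes and on chromosome 16 at 44013852 to 44013977 antisense to an intron of Gramd1c, share 20-base words with transcripts of 1516 and 2382 other genes, so the origin of these reads is uncertain. miR-674-5p had a log2 fold change of -0.92 ± 0.28, with 4 of 4 high-fat libraries below every control. miR-5100, in an intron of Mief2, and miR-2137, in an intron of Zfp185, had log2 fold changes of -1.33 ± 0.41 and -1.78 ± 0.58, and miR-21a-5p one of -0.55 ± 0.17, each with 3 of 4 high-fat libraries below all controls.

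**Figure D2:**
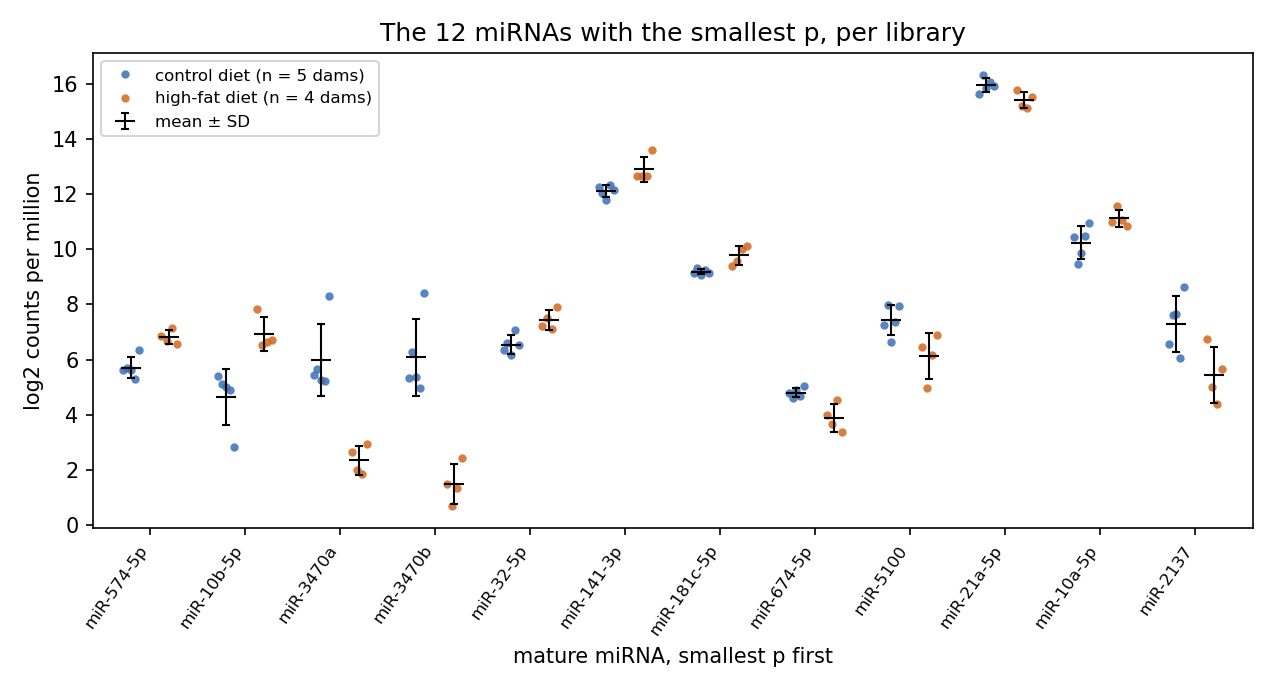
Level on a log2 CPM axis of the 12 mature miRNAs with the smallest p between diets. Each point is 1 dam's library, blue for the control diet (n = 5) and orange for the high-fat diet (n = 4), with the mean and SD of the log2 values in black. The 4 high-fat points of miR-574-5p and miR-10b-5p lie above, and those of miR-3470a and miR-3470b below, all 5 control points.

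Families and cell types were compared with 25 lists of miRNAs, of which 18 had 3 or more tested members. None of the 18 passed an adjusted p of 0.05 by camera against the other miRNAs, with a smallest adjusted p of 0.531, and none did with an estimated correlation or by fry. At an unadjusted p below 0.05, camera gave 1 list and fry 2. Without high-fat library 2, camera called 2 lists, the leukocyte list and the Sfmbt2 intron cluster, both toward higher levels in high-fat milk, and neither passed with an estimated correlation, at adjusted p of 0.905 and 0.780.

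The milk-secreting profile gave no call. The 15 miRNAs of the secretory epithelium list, all tested, made up 58.3% ± 3.21 of control and 57.3% ± 1.58 of high-fat counts, with 9 of 15 fold changes above 0 and none past the threshold. The miR-30 family held 11.2% ± 1.15 and 11.0% ± 0.759, the let-7 family 11.4% ± 1.28 and 11.6% ± 0.940, and the miR-148 and miR-152 family 13.4% ± 1.91 and 14.4% ± 0.865. In the miR-200 family, 4 of 7 members had fold changes above 0 and none passed over all miRNAs. Only miR-141-3p passed when adjusted over the list alone, with a limma-voom adjusted p of 0.0314, uncorrected across lists. Its level was 13.6 log2 CPM in high-fat library 4 and at most 12.7 in the other high-fat libraries. The family as a whole held 9.68% ± 0.856 and 9.92% ± 0.243 of the counts. All 6 members of the miR-15/16 family, known repressors of the cell cycle, had fold changes above 0, led by miR-15a-5p at 0.65 ± 0.23 on the log2 scale. This list had the smallest camera p, 0.0319 unadjusted, which was 0.0630 with an estimated correlation. None of its members passed adjusted over all miRNAs or adjusted over the list alone. All 3 members of the miR-29 family, which targets collagen transcripts, also had fold changes above 0, from 0.04 ± 0.13 for miR-29a-3p to 0.57 ± 0.23 for miR-29c-3p. The cluster of miR-182, miR-96 and miR-183 had 1 of 3 and the miR-17-92 group 4 of 9 fold changes above 0, with none past the threshold.

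miRNAs tied to fat metabolism, inflammation and lactation gave no call either. Of 15 tested members of the lipid and adipocyte list, 7 had fold changes above 0, and the abundant miR-27b-3p and miR-27a-3p, which restrain fat-cell formation, measured -0.05 ± 0.14 and -0.07 ± 0.12 on the log2 scale. In the mammary development list 3 of 7 were above 0. miR-101a-3p had a log2 fold change of 0.31 ± 0.22 and miR-221-3p one of -0.33 ± 0.19. The inflammation-responsive list made up 31.4% ± 0.844 of control and 29.5% ± 0.986 of high-fat counts, a difference of -1.89 percentage points with a two-sided exact permutation p of 0.0317 and an adjusted p of 0.595 over the 25 lists. miR-21a-5p carried most of that difference, while 5 of the 8 members had fold changes above 0. The most abundant member, miR-146b-5p, is also in the secretory epithelium and mammary development lists, so the shares of these lists overlap. In the hypoxia list, miR-210-3p had a log2 fold change of 0.31 ± 0.17. Both tested members of the miR-34 and miR-449 family had fold changes below 0, -0.53 ± 0.38 for miR-34a-5p and -0.25 ± 0.40 for miR-34c-5p. In the Sfmbt2 intron cluster 7 of 11 tested members had fold changes above 0, at mean levels of 20.5 CPM or less. Several of its names share identical counts, so these 11 are not separate measurements. The Dlk1-Dio3 imprinted cluster had no member that passed the count filter, and its 24 detected members made up 0.000880% ± 0.000314 of control and 0.00269% ± 0.00135 of high-fat counts, with an exact permutation p of 0.0476 and an adjusted p of 0.595.

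miRNAs of other cell types were compared to see what else the milk fat carried. The leukocyte list had all 7 tested fold changes above 0, a median log2 fold change of 0.71 that ranged from 0.19 without high-fat library 1 to 1.93 without high-fat library 2, and a camera adjusted p of 0.531. It held 0.0778% ± 0.0179 of control and 0.420% ± 0.562 of high-fat counts, with a two-sided exact permutation p of 0.333. High-fat library 1 held 1.23% (95% Wilson interval 1.22% to 1.25%) and high-fat library 3 0.355% (0.347% to 0.363%), while high-fat libraries 2 and 4 held 0.0317% (0.0300% to 0.0336%) and 0.0607% (0.0573% to 0.0643%), below all 5 controls. These intervals cover counting error only. miR-223-3p, a miRNA of neutrophils and other myeloid cells, had 18330 counts in high-fat library 1 and 1538 in high-fat library 3, against 106 and 153 in the other high-fat libraries and 295 to 549 in controls. miR-142a-5p, found across blood cell lineages, had a log2 fold change of 1.26 ± 1.11, and miR-146a-5p one of 0.71 ± 0.35. Without high-fat libraries 1 and 3, an exclusion chosen after seeing the data, the median log2 fold change of the leukocyte list was -1.01, and 0 miRNAs and 0 lists were called.

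The erythrocyte list, led by miR-451a, made up 0.00799% ± 0.00526 of control and 0.0209% ± 0.0296 of high-fat counts, and high-fat library 3 alone held 0.0650% (0.0616% to 0.0686%). The striated muscle list had no tested member and held 0.00979% (0.00852% to 0.0113%) of high-fat library 3 against at most 0.00137% in any other library. In the endothelial list miR-126a-5p, whose gene lies within Egfl7, measured 3.08 ± 2.26 and 8.16 ± 1.37 CPM. It passed when adjusted over the list alone, with a limma-voom adjusted p of 0.0400 over 2 tested members, uncorrected across lists. Adjusted over all miRNAs it was 0.388. The stromal list held 1.51% ± 0.415 and 1.57% ± 0.679, with 2 of 4 fold changes above 0. The liver list held 0.00409% ± 0.00296 and 0.00265% ± 0.00157, the list of miR-192, miR-194 and miR-215 0.130% ± 0.0391 and 0.0994% ± 0.0255, the neural list 0.0119% ± 0.00238 and 0.0126% ± 0.00123, and the skin list, mostly miR-203-3p, 0.509% ± 0.324 and 0.387% ± 0.0758. None of the 25 list shares differed between diets at an adjusted p of 0.05 by exact permutation. As the smallest possible exact p is 0.0159, a single list could not pass this adjustment even with fully separate diets. The adjusted p values of the inflammation-responsive and Dlk1-Dio3 shares have the same limit. The median, mean and camera direction differed in sign for the let-7, lipid, mammary development lists and for that of miR-192, miR-194 and miR-215.

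**Figure D3:**
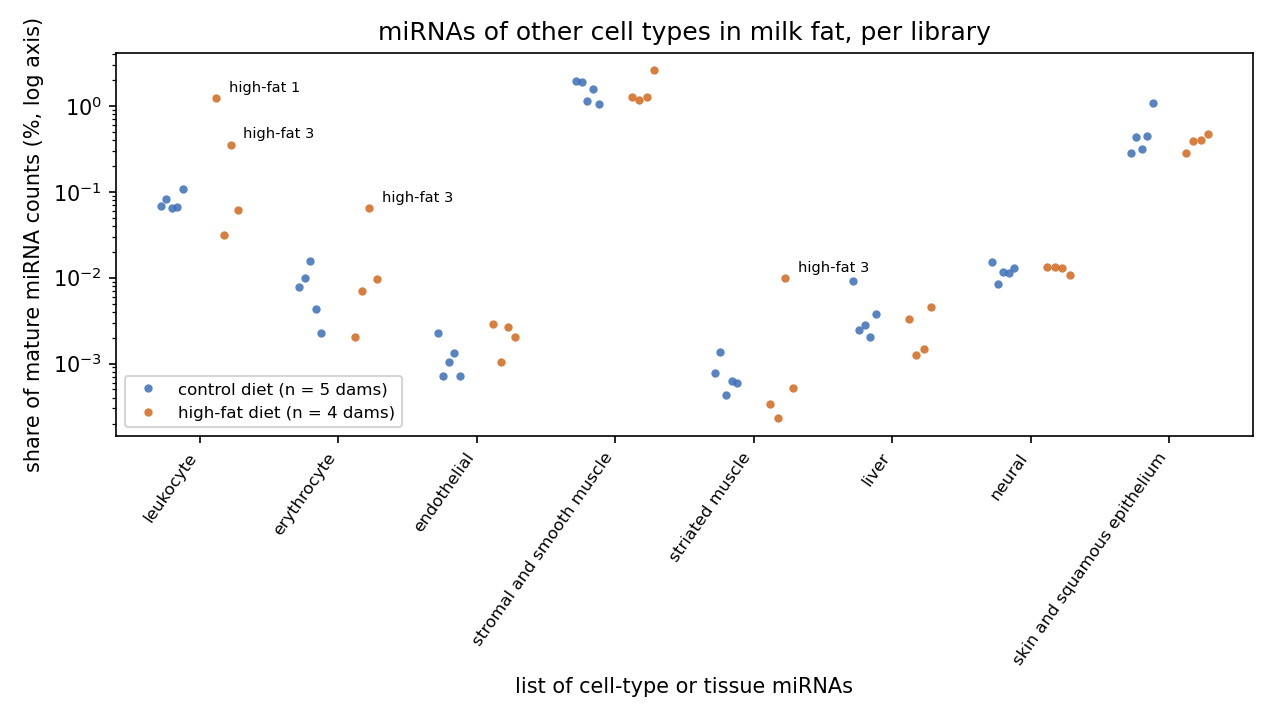
Share of all mature miRNA counts, in percent on a log axis, held by 8 lists of miRNAs of other cell types and tissues. Each point is 1 dam's library, blue for the control diet (n = 5) and orange for the high-fat diet (n = 4). High-fat library 1 held 1.23% leukocyte miRNAs, and high-fat library 3 was the highest for the erythrocyte and striated muscle lists.

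The balance of the 2 arms of a precursor hairpin was compared as the log2 ratio of 5p to 3p counts. None of 102 arm pairs passed an adjusted p of 0.05 by limma, and 13 had an unadjusted p below 0.05. The 5 pairs with the smallest p shared an adjusted p of 0.302 by limma. The log2 ratio of mir-322, on chromosome X at 53054255 to 53054349 between genes, was 0.95 ± 0.28 in control (SD, n = 5) and 1.76 ± 0.37 in high-fat milk (SD, n = 4). mir-32 went from 1.90 ± 0.35 to 2.90 ± 0.46 and mir-574 from -1.31 ± 0.54 to -0.47 ± 0.36, while mir-22, in an exon of Mir22hg and Tlcd2, measured -4.98 ± 0.59 and -5.73 ± 0.36. The ratio of the red cell precursor mir-144 was 1.34 ± 1.01 and -1.42 ± 2.61, and most of its 3p counts came from high-fat library 3.

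The libraries were compared in size and evenness. The mean total count was 1623382 ± 713292 in control and 2540357 ± 922549 in high-fat libraries, with a two-sided exact permutation p of 0.159. Thinned to the smallest total, 464.2 ± 21.4 and 462.1 ± 39.2 mature miRNAs were detected, with an exact p of 0.937. The 10 most abundant miRNAs held 65.2% ± 1.41 and 64.2% ± 0.544 of the counts, with an exact p of 0.254, and the Shannon entropy was 4.81 ± 0.0936 and 4.86 ± 0.0617 bits, with an exact p of 0.365. Without control library 3 the difference in total count, and without control library 5 that in entropy, had an exact p of 0.0286. The median SD of log2 CPM between dams was 0.386 in control and 0.414 in high-fat milk, with an exact p of 0.556.

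The first principal component of log2 CPM held 29.6% of the variance and had mean scores of -4.23 ± 5.07 in control and 5.29 ± 5.13 in high-fat milk, with a two-sided exact permutation p of 0.0317. The scores of the diets overlapped, with high-fat library 2 at -0.936 and control library 1 at -0.887. Its largest loadings were those of miR-3470b and miR-3470a, followed by miR-150-5p, a lymphocyte miRNA, miR-10b-5p and miR-142a-3p. Control library 5 had a score of -13.2 and high-fat library 3 one of 11.2. The exact p was 0.314 without control library 5, 0.0571 without control library 2, 0.190 without miR-3470a and miR-3470b, and 1 over the 100 most abundant miRNAs, where the difference was -0.0107.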

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

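The tests in this part were chosen after the values were seen, apart from the fit without control library 5, which was planned. Of 122 groups of values searched for a library far from the others of its diet, 16 had one, where 1 in 20, or 6.1, is due by chance.

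Leukocyte miRNAs were high in high-fat libraries 1 and 3. The leukocyte share was 15.9 times the control mean in library 1 and 4.56 times in library 3, and in library 1 the myeloid miR-223-5p, too rare elsewhere to be tested, reached 160 counts against at most 8 in a control. Blood carried into the milk is argued against for library 1, where the erythrocyte share was 0.00201% (95% Wilson interval 0.00151% to 0.00268%), below the control mean of 0.00799%. Less epithelial RNA is argued against as well, since the secretory epithelium list held 57.7% (57.6% to 57.7%) there and 52.8% to 60.9% in controls. The stromal share was 0.832 times, the erythrocyte share 0.252 times and the endothelial share 2.40 times the control mean, where less epithelial RNA would raise all 3. The highest of 4 cell-type factors was 62.998 times the lowest. The highest is the flagged leukocyte share itself, so that ratio adds no separate argument. For library 3 blood may be a source, because its erythrocyte share of 0.0650% was the highest of the 9 libraries, and miR-144-3p, untested, reached 79 counts there against at most 6 in a control. An effect of the diet stays open and cannot be told apart from differences between single dams, with 2 of 4 high-fat libraries above every control and the other 2 below. Milk leukocytes in the gland of dam 1 are a candidate explanation that no value here tests, and the wash of the fat layer was meant to remove cells.

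miR-3470a and miR-3470b were lower in all 4 high-fat libraries, and control library 5 lay far above the other controls for miR-3470a with 8.31 log2 CPM against at most 5.69. That library does not account for the difference: without it the log2 fold change of miR-3470a was -3.03 ± 0.33, with an adjusted p of 0.00158 by limma-voom. Both precursors share 20-base words with over 1000 other genes, which is in keeping with reads of repeats counted under these names. If the amount of repeat RNA of all kinds caused the difference, the other 8 tested names that share words with 10 or more genes should be lower too. Of these 8, 5 were lower, with a median log2 fold change of -0.62. The exact permutation p for their mean level was 0.460, which cannot be told apart from chance with 8 names. Whether they hold the same repeat as miR-3470a and miR-3470b was not tested, and both arms of mir-574 are among them. The test therefore cannot decide whether repeat RNA was the cause. The diet stays open: in the main fit of all 9 libraries both miRNAs missed the threshold, with an adjusted p of 0.170 by limma-voom. The limma-voom fit of all 9 libraries with no filter called both, at an adjusted p of 0.0363. With the replicate number as a block limma-voom called both at 0.0334. Control library 5 is alone in its number, so its block term absorbs it and it adds nothing to that diet difference. The block gave -3.02 for miR-3470a, close to the value without that library, and is no separate evidence.

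miR-216a-5p, miR-216b-5p and miR-217-5p, best known from the exocrine pancreas, had 115, 127 and 388 counts in high-fat library 3 and at most 1 count each in any other library. Their genes lie within 1 region of chromosome 11, at 28757012 to 28757083, 28746191 to 28746276 and 28763728 to 28763835. Carry-over from another of the 9 libraries is argued against by the highest miR-217-5p count elsewhere, which was 1. RNA of other tissues stays open: the same library held 146 counts of miR-133a-3p and 38 of miR-1a-3p, miRNAs of striated muscle that reached at most 8 and 2 counts in a control, but it was the highest of the 9 libraries in only 2 of 10 lists, 9 of other cell types and tissues and 1 of an imprinted cluster, and the liver list was not among them. A list of 8 pancreas markers was made after these counts were seen, from general knowledge, and holds both arms of miR-216a, miR-216b and miR-217 with miR-375-3p and miR-802-5p, so it is no independent evidence for that tissue. In high-fat library 3, miR-216b-3p had 5 counts, miR-217-3p 2 and miR-216a-3p 0, and all 3 had 0 elsewhere. miR-375-3p had 8685 counts there and 2462 to 11544 elsewhere, and miR-802-5p 1361 there and at most 65 elsewhere. No biological explanation was tested.

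The remaining values far from the others of their diet follow. In control library 5, miR-181a-5p stood at 15.8 log2 CPM above the others, miR-10b-5p at 3.02 log2 CPM below them, the skin list at 1.08% of counts (1.05% to 1.10%) above, the Shannon entropy at 4.97 bits above and the first principal component at -13.2 below. In high-fat library 4, miR-200a-3p stood at 15.1, miR-143-3p at 14.7 and miR-141-3p at 13.6 log2 CPM above the others, the stromal list at 2.59% (2.57% to 2.61%) above, and the neural list at 0.0108% (0.00943% to 0.0124%) below. In high-fat library 1, miR-10b-5p stood at 7.84 log2 CPM above the others, and the untested miR-338-5p had 38 counts against at most 3 in a control. In high-fat library 3, the miR-30 family stood at 9.91% (9.87% to 9.95%) below the others, and the striated muscle list at 0.00979% above. In control library 1 the liver list stood at 0.00926% (0.00792% to 0.0108%) above the others.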

How the results depend on the processing

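The fit without high-fat libraries 1 and 3, that with identical names merged and the principal components without miR-3470a and miR-3470b were chosen after the data were seen, as were estimated correlations within other alternatives, and the rest before. The planned DESeq2 Wald test was not run. The planned edgeR test is not reported, though an exploratory fit with it was seen. Of 1112 alternative values of single results, 1023 kept their direction and their side of the threshold, 59 reversed, 19 passed the threshold where the reported value did not, 3 no longer passed it, and 8 were counts of calls that changed by more than 1.5 times. At least 1 alternative reversed 6 of 26 miRNAs and 12 of 18 lists, all reported with differences that missed the threshold. Unless a sentence says otherwise, the cause was not tested. List values are medians of log2 fold changes, and a list's direction is that of camera, which can differ in sign from the median.

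The number of miRNAs called was 0 under the median of ratios, library totals, upper quartile and the filter of 10 CPM. It was 4 with no filter (miR-10b-5p, miR-1195, miR-3470a and miR-3470b), 3 with the replicate number as a block (miR-10b-5p, miR-3470a and miR-3470b), 2 with quality weights (miR-574-5p and miR-10b-5p) and 2 at an adjusted p under 0.10. Without single libraries it ranged from 0 to 4, the highest without control library 5. The median log2 fold change of all tested miRNAs moved by less than 0.1 between scalings. Lists called numbered 3 with no filter (miR-15 and miR-16, leukocyte, Dlk1-Dio3), 1 with the block (leukocyte, median 1.505) and 0 to 2 without single libraries, the highest without high-fat library 2, where the leukocyte list had an adjusted p of 0.000533 and the Sfmbt2 intron cluster one of 3.20e-08. With an estimated correlation none of these list calls passed, and their adjusted p ran from 0.616 to 0.947. The small Sfmbt2 p at the preset correlation counts the same reads several times, since names with identical counts entered camera as separate members. The labels do not say that numbers pair dams: deviations of log2 CPM from the mean of the diet correlated across miRNAs, which are not independent, at 0.0537, -0.0884, 0.196 and -0.129 between libraries of the same number. Control library 5 has no high-fat library of its number, so with the block it adds nothing to the diet difference.

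miR-143-3p reversed to -0.0102 by the median of ratios, -0.00212 with no filter, -0.00862 with the filter of 10 CPM, -0.105 with the block, -0.0385 with rows summed and -0.0392 without the most abundant miRNA. let-7f-5p reversed to -0.000309 with rows summed and -0.00239 without the most abundant miRNA. With no filter, the camera direction reversed for lists with medians of 0.0265 for let-7, -0.232 for the cluster of miR-182, -0.0993 for miR-17-92, -0.0563 for lipid, -0.0554 for mammary development and -0.121 for stromal. With the block it reversed for let-7, at a median of 0.0154. None of these medians changed sign.

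Without high-fat libraries 1 and 3, which leaves 2 high-fat libraries, miR-146b-5p reversed to 0.0331, miR-30a-5p to 0.0894 and miR-27b-3p to 0.115. The camera direction reversed for lists with medians of -0.00606 for let-7, -0.0216 for the cluster of miR-182, 0.0371 for lipid, -1.01 for leukocyte, -0.296 for inflammation-responsive and -0.472 for Sfmbt2. Of these medians, only that of the cluster of miR-182 kept its sign.

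Without single libraries, log2 fold changes ranged from -0.115 to 0.151 for let-7f-5p, -0.291 to 0.126 for miR-143-3p, -0.225 to 0.0615 for miR-27b-3p and -0.0766 to 0.166 for let-7i-5p. List medians ranged from 0.0335 to 0.593 for inflammation-responsive, -0.148 to -0.00319 for miR-17-92, -0.127 to 0.0787 for let-7, -0.405 to -0.132 for the cluster of miR-182, -0.126 to 0.0615 for lipid, -0.0793 to 1.42 for Sfmbt2, 0.185 to 1.93 for leukocyte (lowest without high-fat library 1, highest without high-fat library 2), 0.00762 to 0.186 for secretory epithelium, -0.0897 to 0.0856 for miR-30 and -0.507 to 0.990 for erythrocyte, the lowest of which was without high-fat library 3.

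The difference in detected miRNAs reversed to 19.3 unthinned, where depth differs between libraries, and ranged from -14.6 to 17.2 without single libraries. Total counts differed by 464725 to 1198750, the highest without control library 3, and entropy by 0.0289 to 0.0925 bits, the highest without control library 5. The spread between dams differed by -0.0341 to 0.0777. The first principal component differed by -0.0107 over the 100 most abundant miRNAs and by 6.14 without miR-3470a and miR-3470b, which had its largest loadings, and by 4.85 to 11.9 without single libraries, the lowest without control library 5. Arm ratios gave 0 calls under each alternative. Depth limits rare miRNAs most, since a count of 0 in control library 5 allows 0.000358% of the counts.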

Other observations

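The test of names by number and the other splits of the libraries were chosen after the values were seen, and the fold changes come from planned fits, for miRNAs picked here after their values were seen. miR-10a-3p, the other arm of the precursor of miR-10a-5p, had a log2 fold change of 0.81 ± 0.34 with an unadjusted limma-voom p of 0.0366 and an adjusted p of 0.436. The miR-181 family, abundant through miR-181a-5p, had log2 fold changes of 0.20 ± 0.21 for miR-181a-5p, 0.08 ± 0.19 for miR-181b-5p, 0.59 ± 0.17 for miR-181c-5p and 0.28 ± 0.17 for miR-181d-5p, none past the threshold. miR-335-5p had a log2 fold change of 2.51 ± 1.10 (adjusted p 0.441 by limma-voom) and 161 counts in high-fat library 4 and at most 26 in any other library.

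Names with high numbers were compared between diets as a class made up after their values were seen. Of 22 tested names numbered 2000 or above, 17 had a fold change below 0, and their mean level was 5.15 ± 0.62 log2 CPM in control and 4.31 ± 0.37 log2 CPM in high-fat milk, with a two-sided exact permutation p of 0.0317. None of the 22 passed an adjusted p of 0.05 by limma-voom. By camera the p was 7.09e-05 at the preset correlation and 0.0875 with an estimated correlation. The hypothesis that this class as a whole is at a lower level in high-fat milk was left open: without miR-3470a and miR-3470b, 15 of 20 were below 0 with a median log2 fold change of -0.39, and the exact permutation p was 0.0952. miR-1195, untested at the count filter and named after its values were seen, had a log2 fold change of -4.12 ± 0.55 in the fit without a filter.

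Other splits of the 9 libraries were fitted to see how often chance gives as much. For the 32 miRNAs at an unadjusted p below 0.05, 2 of 100 splits into 5 and 4 libraries gave as many, the real one and another with 33, fewer than 5 of 100. The splits treat dams as independent, which housing in pairs within a diet does not ensure, so the housing limits how far chance is excluded. The diets gave 0 adjusted calls of miRNAs, lists and arm pairs, which any of the 100 splits must equal or exceed, so the splits do not test these counts. The highest other split gave 0 miRNAs, 4 lists and 1 arm pair.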
